A study of Mus musculus with 2 samples.

How the data were processed

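H3K27ac chromatin immunoprecipitation was followed by sequencing in stomachs of newborn mice (postnatal day 0, strain B6NTac;B6NCrl/Lap, mixed sex), with 2 biological replicates in 1 group. Per the labels, replicate 1 was made from the stomachs of 15 pups, and fragments of 300 to 500 bp were taken for the libraries. The pool behind replicate 2 was not described by number. A possible control experiment is named per the labels, and its data were not used here.

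The deposited files were peak lists in narrowPeak format on the mouse genome mm10. Per the deposited text files, the list of each replicate was derived from that replicate's filtered alignments together with further input files, 2 for replicate 1 and 1 for replicate 2. The pooled list was derived from both replicates' alignments together with the same 2 further files. The replicated list was derived from both replicates' lists and the pooled list, and each of its 56414 entries was checked to be identical to an entry of the pooled list. The peak caller, its version, its thresholds and the rule that made the replicated list are not given in the sources used here. With the caller unknown, the columns were read from the narrowPeak format and from their values. In each deposited list, the fold enrichment of a peak was taken to be a ratio of the immunoprecipitated over the background or control signal, and the next 2 columns to be a −log10 p-value and a −log10 q-value. Fold and p-value per peak are the authors' own values and were not recomputed. The deposited display score, scaled to at most 1000, was not analysed, and the deposited summit position was used for alternatives only. Lists reached down to a −log10 p of 2.04 in replicate 1 and 2.05 in replicate 2. The share of peaks with a q-value over 0.05 was 4.81% in replicate 1, 8.58% in replicate 2, 5.54% in the pooled list and 0.861% in the replicated list. Reads, alignments and counts were not used here, so the depth of each sample is unknown, and no limit can be given for a gene or region without a peak.

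All values were computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with bedtools 2.31.1 for random placements and samtools 1.23.1 for genome sequence. Genes were taken from GENCODE release M21 and sequence from the RefSeq copy of GRCm38, the assembly also called mm10, and no peak reached past the end of a reference chromosome. The 19 autosomes, X and Y were used, which left out 10 peaks of replicate 1, 5 of replicate 2, 9 of the pooled list and 6 of the replicated list. The annotation gave 21853 protein-coding genes with 54361 distinct transcription start sites. Per list, peaks were counted, merged for the covered length, and described by median length and fold. Shares of peaks have Wilson intervals at 95%, which cover the sampling of peaks and not the variation between animals. A mean with an SD over n = 2 is that of the 2 replicates' own lists, and it can lie below the value of the replicated list, whose peaks have the boundaries called on the pooled reads.

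A promoter was the 1000 bp either side of a start site of a protein-coding transcript. Each peak was put in the first class that applied among promoter, exon, intron and intergenic sequence. Random placement used 100 shuffles of a list within chromosomes, outside assembly gaps of at least 1000 bp. A gene had a promoter peak when a peak overlapped any of its promoters by at least 1 bp, and its promoter fold was the highest among such peaks. The acetylated length of a gene was the sequence covered by peaks whose nearest protein-coding start, within 100 kb, was the gene's. A covered length depends on how much was called, so the fold is given beside it for leading genes and domains.

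Of 32 gene lists, 1 held all 1134 olfactory receptor genes, and the others were fixed lists of markers of cell types, organs and pathways. Of the 407 symbols in the fixed lists, 406 were in the annotation, with intrinsic factor annotated as Gif, and the symbol Loricrin was not matched. The number of members with a promoter peak was compared with that in all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. The same share and the median acetylated length were also set against 10000 random lists of the same size, drawn with replacement from genes outside the list within deciles of the observed over expected CpG frequency, the highest among a gene's promoters. The two-sided p from these lists cannot fall below 0.0002. After adjustment the smallest among the promoter shares was 0.000711, a value that depends on how many lists reached 0.0002. This comparison is a resampling of genes and not an exact test. Genes are not replicates, so both tests describe these peak lists and not the variation between animals, and the shares of each replicate are shown for every list in the figure. In simulated lists of 16 genes among the 21853, the Fisher test called 97 of 100 with strongly raised odds and 1 of 100 unchanged. The length test called 91 of 100 with strongly raised lengths and 4 of 100 unchanged. These calls used p under 0.05 without adjustment over lists. Simulated genes were grouped at random rather than by CpG, and all of them had acetylated sequence. The rates therefore do not carry over to adjusted calls, to smaller lists or to lists with many genes without peaks.

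Genes are named by a fixed rule. Named genes are the 25 with the most acetylated length, with predicted genes (symbols beginning in Gm and digits or ending in Rik) left out, and from each list up to 4 members with the most acetylated length among those with a promoter peak in both replicates and the replicated list, and up to 4 members in list order without a promoter peak in any list. Regions named are the 10 extended domains with the most covered sequence and the 5 peaks with the highest fold. Any other gene is named with words that say so. Reads shared between near-identical copies can leave a gene without peaks, so the alpha-globin pair Hba-a1 and Hba-a2 and the beta-globin Hbb-bs are uncertain.

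Extended domains joined replicated peaks with gaps of at most 12.5 kb and were ranked by the sequence covered by peaks. Peaks of the replicates were called shared when they overlapped by at least 1 bp. The correlation of folds took, for each replicated peak, the strongest overlapping peak of each replicate. Distal peaks lay more than 2.5 kb from any protein-coding start. In the central 200 bp of each, 20 consensus sequences were searched on both strands and compared with as many windows 3 to 20 kb from the peaks, without a pooled peak, matched on GC content in bins of 5 percentage points (36347 pairs). The ratio of shares has a 95% interval from 1000 bootstraps of windows, and a family was called when the interval did not hold 1 and at least 20 flanking windows had the consensus. The families HNF1, NFI, NR2F, RFX and p63 fell under that minimum, which left 15. In 10000 flanking windows with a FOX site written into part of them, a planted ratio of 2.86 was recovered as 2.86. Both values came from the same windows, so this checked the search for the site and not the matching of flanks. Between unplanted sets of flanking windows, 11 of 13 intervals held 1. Unplanted families could thus be called, and the planted ratio was above every ratio called in the replicated list. Small ratios, such as those of TEAD and SOX, are therefore less certain. Intervals were not adjusted over the families.

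The gene lists, consensus sequences, main tests, the naming rule and most alternatives were fixed before the data were examined. Alternatives were a 50% reciprocal overlap, peaks with a −log10 q of at least 5, equal numbers of peaks, summits within 250 bp, distal peaks only, −log10 p in place of fold, promoter windows of 500 bp and 2.5 kb, the pooled list, replicated peaks with a fold in the upper part of the list (above the median of 4.37), assignment within 50 kb to the nearest or to every start, joining within 5 kb, ranking by fold, domains without promoter peaks, windows of 400 bp or at the summit, shuffled sequence that kept dinucleotides, and each replicate's list alone. Alternatives added after seeing the data used only replicated peaks that both replicates overlapped, matched random lists also on the span between neighbouring start sites in quintiles, and left out each replicate in turn for the consensus sequences. Text files that describe the deposit hold no measurement and were read for the origin of the lists only.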

Results

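Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the mouse stomach on the day of birth. Both samples belonged to 1 group of 2 biological replicates, each a pool of stomachs from pups of both sexes. Replicate 1 came from 15 pups, and the size of the pool behind replicate 2 was not stated. With a single tissue and age, nothing could be compared between conditions, so the mark was compared between kinds of gene, between places in the genome, and between the replicates. The newborn stomach holds a glandular part, a squamous forestomach, smooth muscle, mesenchyme, nerves and vessels, and the question was which of their marker genes carried the mark. The deposited lists held 100949 peaks covering 48.9 Mb in replicate 1 and 62345 peaks covering 32.7 Mb in replicate 2. The authors' replicated list, from which values are given unless another list is named, held 56414 peaks covering 45.1 Mb with a median length of 552 bp. Its median fold enrichment was 4.37 and its highest 56.99. Acetylated lengths of single genes varied between the replicates. Of the 85 genes named below for the most acetylated sequence of their list, 77 had more in replicate 1, and it was over 1.5 times that of the other replicate in 35 of these and in 2 of the 8 others. Read counts were not available here, so the sequencing depth of either sample is unknown, and a gene without a peak was not detected at that unknown depth rather than shown to lack the mark. The lists come from stomach as a whole, so a peak cannot be assigned to a cell type. For the same reason, a missing peak does not show the state of a gene in rare cells.

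Regulators of the gastric epithelium carried the mark at their promoters without exception. All 19 transcription factors of this list had a promoter peak, among them Gata4, Grhl2, Elf3 and Foxa1, and also Sox2, the regulator of foregut fate, which was named after its values were seen. Gata4 on chromosome 14 (63198922 to 63271692, mm10), a zinc finger factor of gut endoderm, had 22655 bp of acetylated sequence assigned to it, from 22960 bp in replicate 1 and 15975 bp in replicate 2 (mean 19468 ± 4939 bp, SD, n = 2). Grhl2, a regulator of epithelial junctions on chromosome 15 (37233036 to 37363569), had 19311 bp and a promoter fold of 20.6. Elf3, an epithelial ETS factor, had 18587 bp, and the pioneer factor Foxa1 had 18105 bp. The share of 100% exceeded the 55.3% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 0.000148). It also exceeded the 67.5% of random lists with equally CpG-rich promoters (adjusted p = 0.000711, not an exact test). That value comes from the smallest p that 10000 random lists could give. Replicate 1 had a promoter peak at 19 of the genes and replicate 2 at 17, lacking Nkx6-3 and Pdx1, which are named because they were the missing 2. The list's median acetylated length was 7541 bp against a mean of 1188 bp in random lists (adjusted p = 0.00128, not an exact test), a call lost when peaks were counted for every start within 50 kb (0.0549).

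Genes of the mature gastric cell types were marked unevenly. Of 16 genes of surface and neck mucous cells, 10 had a promoter peak (11 in replicate 1 and 10 in replicate 2). Agr2, needed for mucin folding, had 7029 bp of acetylated sequence (mean of the replicates 5235 ± 1217 bp, SD, n = 2), and the stomach tight junction gene Cldn18 had 6996 bp (5328 ± 1633 bp). The membrane mucin gene Muc1 had 5250 bp and the trefoil peptide gene Tff1 4786 bp. The gastrokine genes Gkn1, Gkn2 and Gkn3 and the protease gene Ctse had no promoter peak in any list. The share of 62.5% did not differ from that of other genes (Fisher's exact test, adjusted p = 0.676), but promoters as poor in CpG as these had a peak in 20.3% of random lists' members (adjusted p = 0.00116).

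Of 13 parietal cell genes, 7 had a promoter peak in the replicated list and in each replicate. These included the potassium channel genes Kcnj15 (8198 bp of acetylated sequence) and Kcnq1 (7132 bp), the chloride transporter gene Slc26a9 (5938 bp) and the creatine kinase gene Ckb (5489 bp). Replicate 1 exceeded replicate 2 at all 4, with 11298 against 4643 bp at Kcnj15, 7714 against 4280 bp at Kcnq1 and 7124 against 2056 bp at Slc26a9. Atp4b, which encodes a subunit of the acid pump, had none in any list, nor had Kcne2, Aqp4 and Hrh2. The share of 53.8% differed neither from other genes nor from random lists (adjusted p = 1 by Fisher's exact test and 0.686), while the median acetylated length of 3412 bp exceeded the random mean of 389 bp (adjusted p = 0.004), a call lost when peaks were counted for every start within 50 kb (0.371). Of 7 chief cell genes 2 had a promoter peak, 3 in replicate 1 and 1 in replicate 2. The milk-clotting protease gene Cym was one of them, with 5162 bp of acetylated sequence (3945 ± 235 bp over the replicates, SD, n = 2). The pepsinogen gene Pgc, the intrinsic factor gene Gif, Chia1 and Lipf had no promoter peak in any list. The chief cell share of 28.6% did not differ from that of other genes (Fisher's exact test, adjusted p = 0.301) or from the 14.5% of random lists (adjusted p = 0.704).

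Marker genes of hormone-producing cells mostly lacked promoter peaks. Among 18 enteroendocrine genes the only one with a promoter peak was Isl1, a homeobox gene of several lineages, with a fold of 8.82 (7.32 in replicate 1 and 9.52 in replicate 2). Chga, Chgb, Gast and Sst had none, and 16 of the 18 had none in any list. Replicate 1 had a promoter peak at 1 of them and replicate 2 at 2. The share of 5.56% was below that of other genes (Fisher's exact test, adjusted p = 0.000122) and below the 56.8% of CpG-matched random lists (adjusted p = 0.000711, the smallest possible). Marker genes of enteric nerve cells and glia gave a similar result. Of 20 genes of enteric neurons and glia, 3 had a promoter peak (5 in replicate 1 and 3 in replicate 2), namely Hand2 (13424 bp), Erbb3 (7457 bp, fold 21.2) and Ednrb (4912 bp), which encode a transcription factor also active in mesenchyme, a neuregulin receptor and an endothelin receptor. Phox2a, Plp1, S100b and Elavl3 had none in any list. The share of 15.0% lay below that of other genes (Fisher's exact test, adjusted p = 0.00148) and of random lists (65.4%, adjusted p = 0.000711). The pooled list, made from the reads of both replicates together, had promoter peaks at 8 of the 20, which did not differ from other genes (Fisher's exact test, adjusted p = 0.148).

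Visceral smooth muscle was marked throughout. All 16 of its genes had a promoter peak in the replicated list and in each replicate. Mylk, which encodes the kinase that starts smooth muscle contraction (chromosome 16, 34745210 to 35002420), had 29176 bp of acetylated sequence (24474 ± 4366 bp over the replicates, SD, n = 2) and a promoter fold of 17.1. Synpo2, an actin-binding protein gene, had 28266 bp, the LIM protein gene Csrp1 17492 bp and the smoothelin gene Smtn 14118 bp. The share exceeded that of other genes (Fisher's exact test, adjusted p = 0.000688) and the 42.5% of random lists (adjusted p = 0.000711), and the median acetylated length of 8581 bp exceeded their mean of 418 bp (adjusted p = 0.00128).

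Genes of the gut mesenchyme were marked as well. Fibroblast matrix genes had a promoter peak at 13 of 13 (12 in replicate 2), with 27990 bp of acetylated sequence at the collagen gene Col1a1 (23389 ± 3999 bp, SD, n = 2), 13558 bp at Fbln1, 12792 bp at Sparc and 11987 bp at Col1a2. This share exceeded that of other genes (Fisher's exact test, adjusted p = 0.00249) and the 36.3% of random lists (adjusted p = 0.000711). Among 17 mesenchymal transcription factors, 15 had a promoter peak (14 in replicate 2). Barx1, the stomach-specific mesenchymal homeobox gene (chromosome 13, 48662998 to 48666507), had 14781 bp (11900 ± 633 bp) and a promoter fold of 14.2. The forkhead gene Foxf1 had 18193 bp and a fold of 24.6, and the homeobox genes Meis1 and Meis2 had 20258 and 19551 bp. Nkx2-5, a marker of the pyloric sphincter, and Hand1 had no promoter peak in any list. The share of 88.2% exceeded that of other genes (Fisher's exact test, adjusted p = 0.0115) but not the 83.0% of random lists with equally CpG-rich promoters (adjusted p = 0.919).

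The forestomach, which keeps a squamous lining in mice, was represented by 14 of 16 genes. Pitx1, a homeobox gene on chromosome 13 (55825051 to 55836192), had 38008 bp of acetylated sequence (34587 ± 6473 bp, SD, n = 2) and a promoter fold of 21.2. Grhl3, a regulator of squamous differentiation, had 14826 bp, the keratin gene Krt13 6491 bp and the hemidesmosome collagen gene Col17a1 3437 bp. Replicate 1 exceeded replicate 2 at all 4, with 39164 against 30010 bp at Pitx1 and 6738 against 2111 bp at Krt13. Krt6a and Sprr3 had no promoter peak in any list. The share of 87.5% exceeded that of other genes (Fisher's exact test, adjusted p = 0.0183) and the 29.6% of random lists (adjusted p = 0.000711). The first of these calls was lost in each replicate taken alone, where 13 and 11 genes had a promoter peak.

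Among minor cell populations, interstitial cells of Cajal, the pacemakers of the gut, had a promoter peak at 3 of 4 genes, namely Ano1 (7341 bp, from 11346 bp in replicate 1 and 4083 bp in replicate 2), Etv1 (2915 bp) and Kit (1901 bp), and none at Prkcq. Endothelium had one at 10 of 14, led by Egfl7 (14752 bp), Pecam1 (4679 bp), Esam (3866 bp) and Cdh5 (2928 bp), and at 12 in replicate 1, 10 in replicate 2 and 14 in the pooled list. Immune cells had one at 8 of 14, with 7 and 6 in the replicates. Runx1 (13426 bp), Fcer1g (2291 bp), Cd68 (1332 bp) and Spi1 (354 bp) had one, while the T cell gene Cd3e, the B cell gene Cd19, Runx3 and Itgam had none in any list. These 3 lists did not differ from other genes (Fisher's exact test, adjusted p = 0.676, 0.328 and 1). In the pooled list the endothelial share was above other genes (Fisher's exact test, adjusted p = 0.00266), and among peaks with a fold above the median the immune share was below (0.0230). Erythroid genes had a promoter peak at 3 of 13, also in each replicate, among them Tal1 and Gypa, but not Gata1 or Hbb-bs in any list. Hba-a1 and Hba-a2, near-identical copies that short reads cannot always tell apart, also lacked one, which is uncertain for that reason, as it is for Hbb-bs. Mesothelial genes had a promoter peak at 1 of 8 (2 in replicate 1 and 1 in replicate 2), Krt19, a keratin gene shared with other epithelia (17381 bp), and none at Upk3b, Upk1b, Msln or Lrrn4. Erythroid and mesothelial shares were below that of other genes (Fisher's exact test, adjusted p = 0.0409 and 0.0416) but not below random lists (adjusted p = 0.919 and 0.405). The erythroid call was lost under 4 alternatives, 1 of them without replicate 1, and the mesothelial one under 3, 1 of them without replicate 2.

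Genes of neighbouring and distant organs were mostly without promoter peaks. The intestinal regulators Cdx1 and Cdx2, the stem cell gene Lgr5 and Olfm4 had none in any list, and of 15 intestinal genes the 2 with a peak were Vil1 (3617 bp) and Slc5a1 (631 bp), with 2 in each replicate. The pancreatic genes Ptf1a, Cpa1, Cela2a and Pnlip had none, with a peak at 2 of 13 genes, and none of the 13 had a peak in replicate 2. The liver genes Alb, Afp, Apoa1 and Apob had none, and the 2 liver genes of 14 with a peak were the endodermal regulator Hnf1a (8250 bp, fold 10.3) and Apoh (4347 bp), with 3 in replicate 1 and 2 in replicate 2. These 3 shares were below that of other genes (Fisher's exact test, adjusted p = 0.00282, 0.00856 and 0.00474), although random lists with equally CpG-poor promoters had only 30.8, 33.2 and 26.3%, from which none of the 3 differed (adjusted p = 0.22, 0.273 and 0.633).

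In lung epithelium, Hopx, Abca3 and Ager had a promoter peak and Sftpc, Sftpb, Sftpa1 and Nkx2-1 did not (3 of 10 genes, 5 in replicate 1 and 3 in replicate 2). Heart muscle had one at Tnnt2, Myh7 and Myl7 and none at Myh6, Nppa, Nppb and Tnni3 (3 of 11, also in each replicate). Skeletal muscle had one at Tnni2, Ckm and Mylpf and none at the determination genes Myod1, Myog, Myf5 and Myf6 (3 of 12, and 4 in each replicate). None of these 3 lists differed from other genes (Fisher's exact test, adjusted p = 0.163, 0.106 and 0.0646). No forebrain gene of 12 had a promoter peak, with Neurod6, Tbr1, Foxg1 and Emx1 lacking one in every list, and no kidney gene of 10 did, with Pax2, Pax8, Nphs1 and Nphs2 lacking one in every list. Replicate 1 and the pooled list had one at 2 forebrain genes, Satb2 and Dlx1, and at 1 kidney gene, Slc34a1, all named after their values were seen. The forebrain list was below other genes (Fisher's exact test, adjusted p = 0.000399) and below the 77.1% of random lists (adjusted p = 0.000711), and the kidney list likewise (adjusted p = 0.00143, and 0.00907 against 37.8%). Of 12 germ cell genes, Dazl had a promoter peak and Ddx4, Mael, Sycp1 and Sycp3 had none (Fisher's exact test, adjusted p = 0.00416). The germ cell call was lost without replicate 2, where 3 of the 12 genes had a promoter peak. Of 1134 olfactory receptor genes, 2 (0.176%) had a promoter peak (3 in replicate 1 and 2 in replicate 2), against 11.3% in random lists.

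**Figure D1:**
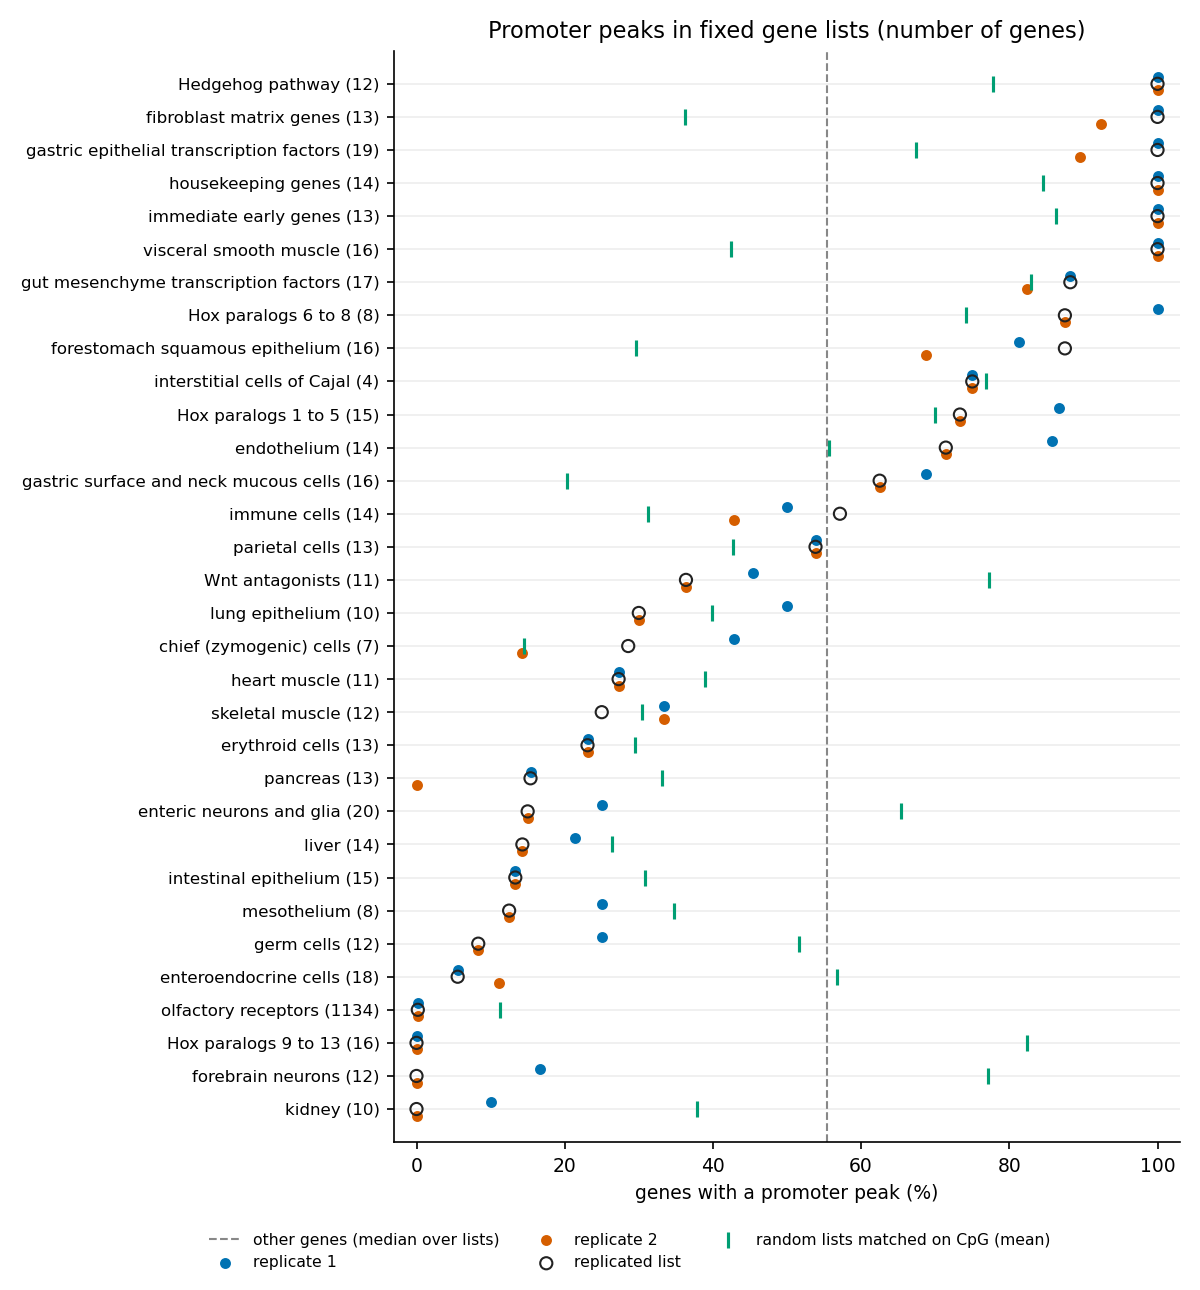
Genes with a promoter peak (%, x axis) in each of 32 fixed lists (y axis, number of genes in brackets), in the replicated list (open circles) and in each replicate (filled points), with the share in other genes (dashed line) and the mean of CpG-matched random lists (green ticks). Gastric epithelial transcription factors, smooth muscle and fibroblast genes stood at 100% in the replicated list with their random lists between 36.3 and 67.5%. Hedgehog, immediate early and housekeeping genes also stood at 100%, with random lists at 77.8, 86.4 and 84.5%. Hox paralogs 9 to 13, forebrain and kidney genes stood at 0%.

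Signalling genes of stomach development were compared in the same way. All 12 Hedgehog pathway genes had a promoter peak in the replicated list and in each replicate. The receptor gene Ptch1, itself a target of the pathway, had 19057 bp of acetylated sequence (17320 ± 2519 bp, SD, n = 2) and a promoter fold of 22.01, Gli2 had 13120 bp, the ligand gene Shh 12437 bp with a fold of 5.64, and the co-receptor gene Boc 10585 bp. The share exceeded that of other genes (Fisher's exact test, adjusted p = 0.00249) but not that of random lists, which had 77.8% (adjusted p = 0.145), while the median acetylated length of 6182 bp exceeded their mean of 1545 bp (adjusted p = 0.00366), a call lost when peaks were counted for every start within 50 kb (0.338). Wnt antagonists had a promoter peak at 4 of 11 (5 in replicate 1 and 4 in replicate 2). These were Dkk3 (10066 bp), Sfrp1 (7136 bp), Sfrp2 (1905 bp) and Axin2 (5627 bp), the last of them a Wnt target with a promoter fold of 33.3 (25.9 and 32.5 in the replicates), while Sfrp4, Sfrp5, Dkk1 and Dkk2 had none in any list. Their share did not differ from other genes (Fisher's exact test, adjusted p = 0.29) and was below the 77.3% of random lists (adjusted p = 0.0153).

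Hox genes were read in 3 groups of paralogs, which were not tested against each other. No gene of paralogs 9 to 13, the posterior group, had a promoter peak in any list, and Hoxa9, Hoxa10, Hoxa11 and Hoxa13 were among these 16. Of paralogs 1 to 5, 11 of 15 had one (13 in replicate 1 and 11 in replicate 2), with 23653 bp of acetylated sequence at Hoxb3 (21240 ± 1763 bp, SD, n = 2), 13355 bp at Hoxc4, 10381 bp at Hoxa2 and 8963 bp at Hoxb4, and none in any list at Hoxb1 and Hoxd1. Of paralogs 6 to 8, 7 of 8 had one (8 and 7 in the replicates), with 5375 bp at Hoxc6, 4659 bp at Hoxb6, 4296 bp at Hoxb7 and 2884 bp at Hoxa6. The posterior group was below other genes (Fisher's exact test, adjusted p = 3.95e-05) and below random lists, which had 82.4% (adjusted p = 0.000711). Neither of the other groups differed from other genes in promoter share (Fisher's exact test, adjusted p = 0.255 and 0.115), although paralogs 6 to 8 were above them in the pooled list (0.0393) and in replicate 1 alone (0.0435). The median acetylated length of paralogs 1 to 5, 6766 bp, exceeded the random mean of 1159 bp (adjusted p = 0.00128, not an exact test). That of paralogs 6 to 8, 2461 bp, did not differ from 1404 bp (adjusted p = 0.339, not an exact test), but was above random lists matched also on span (0.0261) and when peaks were counted for every start within 50 kb (0.00128).

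**Figure D2:**
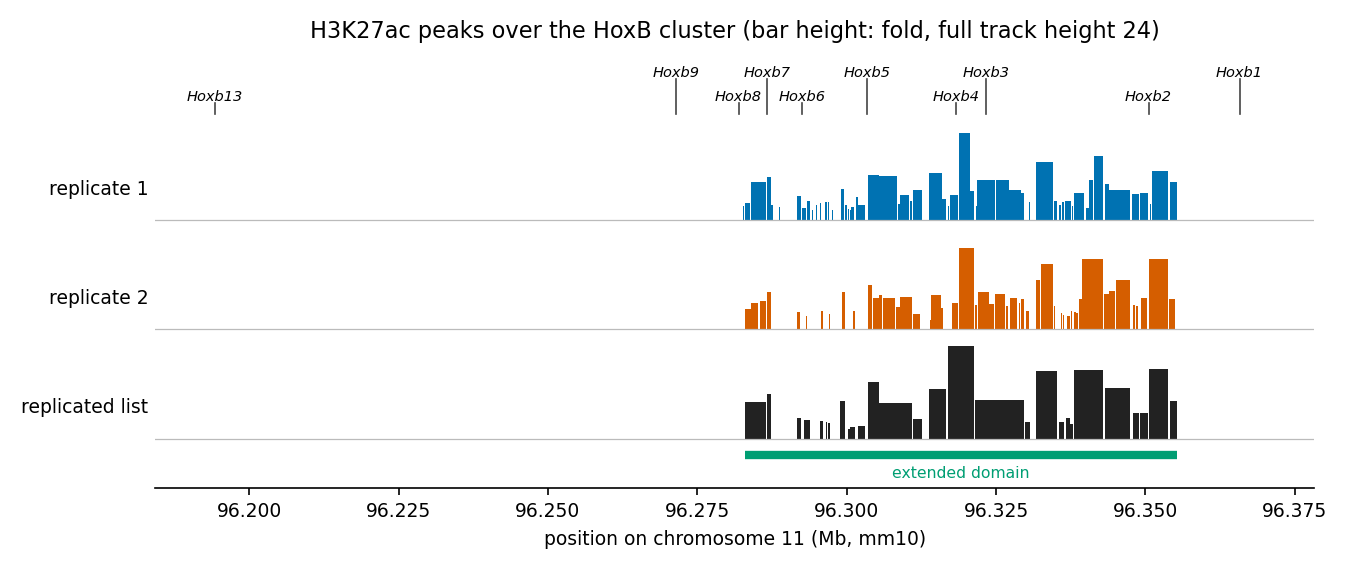
Peaks over the HoxB cluster (x axis, position on chromosome 11 in Mb, mm10; bar height, fold enrichment) in replicate 1, replicate 2 and the replicated list, with the start of each Hoxb gene above and the extended domain below. Peaks lay along the stretch from Hoxb7 to Hoxb2, with a gap between Hoxb7 and Hoxb6 (96287298 to 96291648 in the replicated list). None reached the starts of Hoxb13, Hoxb9 and Hoxb8 on one side or that of Hoxb1 on the other. The start of Hoxb8 (96281905) lay close to the first peak of replicate 1 (from 96282696).

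As reference lists, immediate early genes had a promoter peak at 13 of 13 and housekeeping genes at 14 of 14, also in each replicate. Fosl2, an AP-1 subunit gene, had 36685 bp of acetylated sequence and a fold of 42.5, Fos 22623 bp, Dusp1 19543 bp and Ier2 13619 bp. Actb had 17247 bp, Ywhaz 16672 bp, Eef1a1 7510 bp and Ubc 6826 bp. Both shares exceeded that of other genes (Fisher's exact test, adjusted p = 0.00249 and 0.00171) but not those of random lists, 86.4 and 84.5% (adjusted p = 0.439 and 0.318). In median acetylated length the immediate early genes, with 10535 bp, exceeded the random mean of 1798 bp (adjusted p = 0.00128, not an exact test). The housekeeping genes, with 3070 bp, did not differ from 1676 bp (adjusted p = 0.156, not an exact test), but were above random lists matched also on span (0.0256) and with every start within 50 kb (0.0486). Over the 32 lists, 8 were above other genes in promoter share and 12 below, and 9 were above random lists in acetylated length and 2 below, the 2 being forebrain neurons and Hox paralogs 9 to 13 (adjusted p = 0.0239 and 0.00427, not an exact test). The forebrain call was lost with folds above the median (adjusted p = 0.0980, not an exact test) and that of the Hox paralogs with every start within 50 kb (0.352).

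Ranked over the whole genome, the gene with the most acetylated sequence assigned to it was Foxp1, a forkhead repressor gene on chromosome 6 (98925338 to 99522721). It had 61774 bp in 80 peaks (56110 ± 18329 bp over the replicates, SD, n = 2) and a promoter fold of 38.2. Rbpms, an RNA-binding protein gene of smooth muscle and heart on chromosome 8 (33782643 to 33929863), had 56998 bp (48434 ± 8172 bp). The others among the leading 25, apart from predicted genes, ranged from 48191 bp at Sorbs1 to 36570 bp at Rara. Between them, in order, were Irf2bp2 (47746 bp), Casz1 (47655 bp), Tns1 (46764 bp), Zmiz1 (46393 bp), Zmynd8 (45890 bp, fold 46.0), Myh9 (44567 bp), Zfp36l2 (44388 bp), Ablim1, Il17b (42905 bp), Gse1, Dab2ip, Rxra (41221 bp), Actn4, Sik1, Sept9, Pitx1, Chd2, Svil, Shb, Fosl2 and Ncor2. Of the 25, 20 were also among the leading 25 without replicate 1 and 22 without replicate 2, and 12 when peaks were counted for every start within 50 kb. Each of the 25 had a promoter peak in both replicates, and in each the length was greater in replicate 1 than in replicate 2. Sequence was assigned to protein-coding starts only. The length of Il17b may therefore include sequence around the non-coding gene Carmn, named after its values were seen, which lies in the same domain.

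When neighbouring replicated peaks were joined, 18902 domains resulted, of which 8157 held 1 peak and 701 had at least 10 kb covered by peaks. The domain with the most covered sequence lay over Rbpms (chromosome 8, 33774991 to 33931951) with 68525 bp in 76 peaks (58182 ± 9699 bp over the replicates, SD, n = 2). The HoxB domain came next (chromosome 11, 96282957 to 96355232), holding the starts of Hoxb2 to Hoxb7, with 56929 bp in 28 peaks and a mean fold of 10.1 (50112 ± 6797 bp). The domain over Il17b, Pcyox1l and Grpel2 (chromosome 18, 61609229 to 61729868) had 55211 bp and a mean fold of 12.6. Within it also lay the non-coding gene Carmn (61649625 to 61665537), named after its values were seen. Its promoter fold was 22.97, against 7.13 at Il17b. The domains over Irf2bp2 (chromosome 8, 126516341 to 126669940), Ahdc1 and Wasf2 (chromosome 4, 133011249 to 133132589), Sik1 (chromosome 17, 31722419 to 31913660), and Ski and Faap20 (chromosome 4, 155114933 to 155252793) had 53539, 52094, 49971 and 49971 bp. The domain over Rara, Cdc6 and Wipf2 (chromosome 11, 98863011 to 98982585) had 49829 bp, and the one over Lsp1, Mrpl23, Syt8, Tnni2 and Tnnt3 (chromosome 7, 142429529 to 142543400) had 48236 bp. The domain ranked 10 (chromosome 12, 79879181 to 80018220) had 47342 bp and held no protein-coding start, the nearest being that of Zfp36l1 at 94774 bp. Of the 25 leading domains, 15 were shared with the leading 25 of replicate 1 and 22 with those of replicate 2.

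The strongest single peak lay at the promoter of the splicing kinase gene Clk1 (chromosome 1, 58423125 to 58424132), with a fold of 56.99 (48.7 in replicate 1 and 47.9 in replicate 2). It was followed by a peak over an exon 1043 bp from the start of Rhof (chromosome 5, 123133735 to 123140654), with a fold of 55.6 (46.1 and 51.0). The promoter peaks of Hmgb2 (chromosome 8, 57511863 to 57512948), Erbin (chromosome 13, 103918572 to 103922807) and Sp3 (chromosome 2, 72978375 to 72981361) had folds of 53.6, 53.3 and 52.4.

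Across the genome, 29.5% of replicated peaks (16645 of 56408 on the main chromosomes) lay at a protein-coding promoter, against 3.65% of peaks placed at random and at most 3.84% in 100 placements. Exons held 10.6%, introns 38.2% and intergenic sequence 21.7%, where random placement gave 9.89, 36.9 and 49.5%. Promoter peaks were stronger and longer than intronic ones, with a median fold of 7.25 against 3.94 and a median length of 812 against 475 bp, and they made up 40.3% of the covered sequence. Promoter was the first class tried, and a longer peak overlaps a promoter window more easily. Part of the difference in length may therefore come from the class rule. The promoter share was 21.6% in replicate 1 and 30.5% in replicate 2 (26.04 ± 6.34%, SD, n = 2). Of 21853 protein-coding genes, 12098 (55.4%) had a promoter peak. The share was 58.4% in replicate 1 and 54.0% in replicate 2 (56.2 ± 3.11%). Both replicates marked 11625 genes, replicate 1 alone 1147 and replicate 2 alone 185.

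Distal peaks, more than 2.5 kb from any protein-coding start, numbered 36394, and their sequences were searched for consensus sites of transcription factor families. Sites of the muscle factors MEF2 and SRF (the CArG box) were enriched over flanking sequence of the same GC content, with ratios of 1.51 (95% interval 1.13 to 2.05) and 1.36 (1.18 to 1.60). AP-1 sites were present in 4.38% of windows and 3.45% of flanks (ratio 1.27, 1.18 to 1.37), and FOX sites in 7.52 and 5.97% (1.26, 1.19 to 1.33). E-boxes of the CAGCTG type, bound by tissue-restricted helix-loop-helix factors, were present in 15.1 and 12.3% (1.23, 1.18 to 1.27). TEAD and SOX sites had ratios of 1.12 (1.08 to 1.17) and 1.11 (1.07 to 1.16). Each of these 7 ratios was above 1 in both replicates' own distal peaks, at 1.24 and 1.46 for MEF2, 1.28 and 1.15 for SRF, 1.21 and 1.17 for AP-1, and 1.16 and 1.15 for FOX. The interval held 1 for MEF2 in replicate 1 and for SRF in replicate 2. The AP-1 and SRF enrichment was absent when windows were centred on the peak summit, with ratios of 0.970 and 0.981, and against shuffled sequence the ratios were 1.04 for AP-1, 0.891 for SRF and 1.02 for SOX, none of them called. The intervals of 8 further families held 1 in the replicated list, among them HNF4 (1.23), GATA (1.09), CDX (0.965) and CTCF (0.70). CTCF sites were below flanks in each replicate's own distal peaks, with ratios of 0.514 (0.384 to 0.671) and 0.416 (0.275 to 0.580). The long GATA consensus was above flanks in replicate 1 (1.205, 1.13 to 1.29) and not called in replicate 2 (1.09). Intervals cover the sampling of windows in these lists and not the variation between animals.

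**Figure D3:**
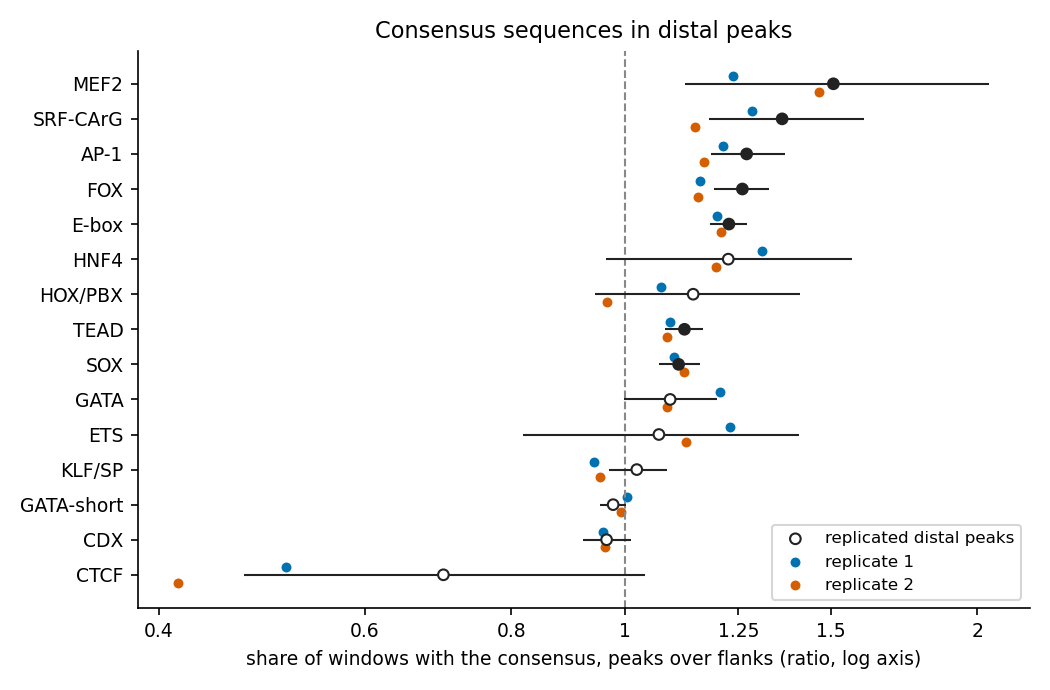
Share of 200 bp windows with each consensus in distal replicated peaks divided by that in GC-matched flanks (x axis, ratio on a log axis), by factor family (y axis), with 95% bootstrap intervals; filled circles mark intervals above 1, and coloured points give each replicate's own distal peaks. MEF2, SRF, AP-1, FOX, E-box, TEAD and SOX sites lay above 1, and CTCF had a ratio of 0.70 with an interval that held 1, and 0.514 and 0.416 in the replicates.

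The replicates shared most of their strong peaks. Of replicate 2's peaks, 84.5% (95% Wilson interval 84.2 to 84.8%) were overlapped by a peak of replicate 1, and of replicate 1's peaks 48.7% (48.4 to 49.0%) by one of replicate 2. Random placement gave 3.79 and 2.68%, at most 4.02 and 2.85% in 100 placements. The Jaccard index of the covered sequence was 0.495 against 0.00856 at random. Across the 42668 replicated peaks found in both, Spearman's rho of the fold enrichment was 0.755, without a p-value since peaks are not independent replicates. The median log2 ratio of replicate 1 to replicate 2 was -0.01 with an SD of 0.40. Peaks called in 1 replicate only could not enter this comparison. In the 25509 distal peaks found in both, rho was 0.589.

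**Figure D4:**
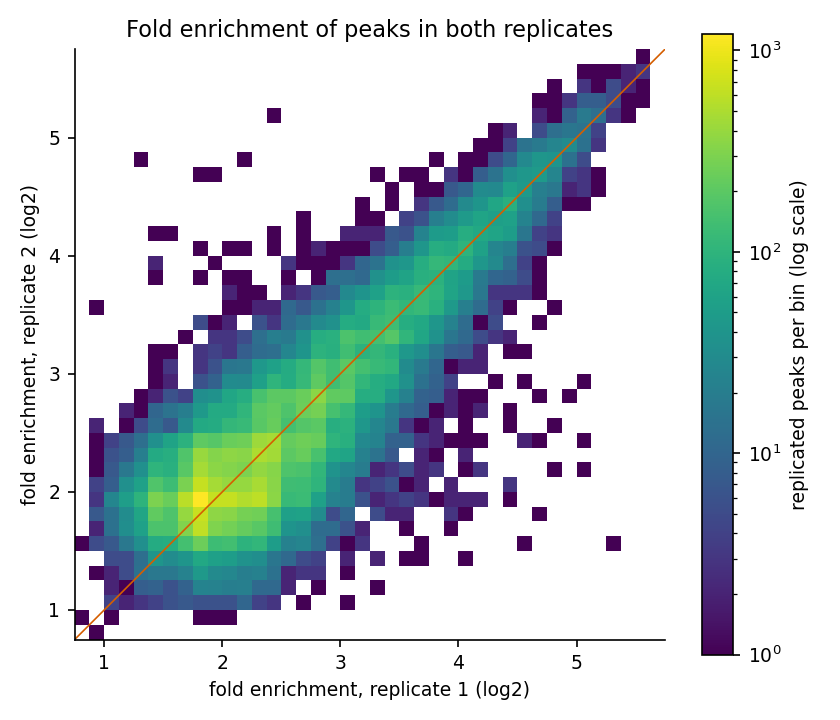
Fold enrichment of the 42668 replicated peaks found in both replicates, replicate 1 (x axis, log2) against replicate 2 (y axis, log2), with the number of peaks per bin as colour on a log scale and equality as a line. Peaks lay along the line, with a median log2 ratio of -0.01 and a Spearman's rho of 0.755 (0.589 in distal peaks).

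Peaks found in 1 replicate only had lower folds than shared ones. In the lowest quintile of replicate 1 by fold enrichment, 80.0% of peaks had no overlap in replicate 2, in the quintile below the highest 34.04% (6872 peaks), and in the highest 2.65% (535 peaks). In replicate 2 the shares were 31.9, 3.11 and 0.0401% (5 of 12468). The median fold of unshared peaks was 3.18 against 4.77 for shared ones in replicate 1, and 3.58 against 4.54 in replicate 2. Unshared peaks lay at promoters in 10.3% of cases in replicate 1 and 12.9% in replicate 2, where shared peaks did so in 33.4 and 33.8%. In the replicated list, 94.7% of peaks were overlapped by replicate 1, 79.6% by replicate 2, and 24.4% (13740) were not overlapped by both.

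**Figure D5:**
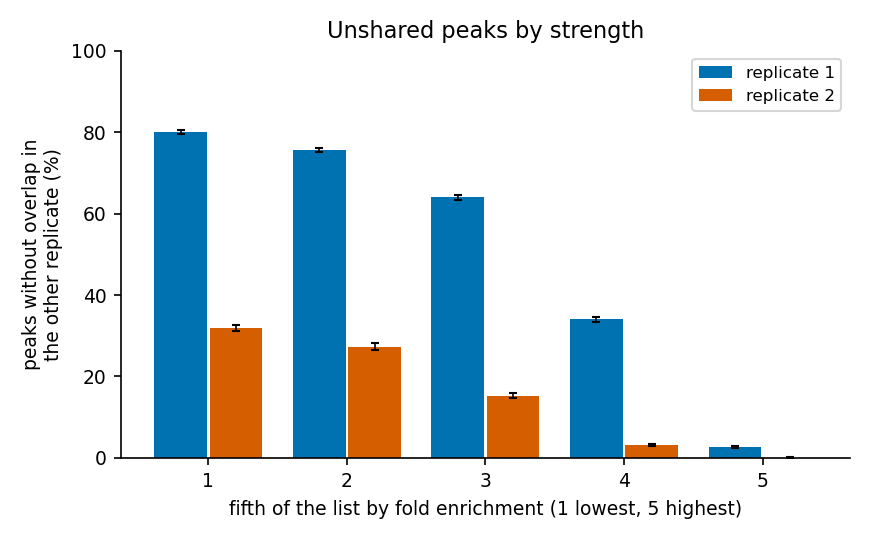
Peaks without overlap in the other replicate (%, y axis) by quintile of each list ordered by fold enrichment (x axis, 1 lowest and 5 highest), with 95% Wilson intervals. The share fell from 80.0 to 2.65% in replicate 1 and from 31.9 to 0.0401% in replicate 2.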

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

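Some alternatives in this section were chosen only after results were seen. These were replicated peaks that both replicates overlapped, random lists matched on CpG and span, and consensus sequences without each replicate. The cause of the changes below was not tested, unless one is given.

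Over all lists and alternatives, 206 promoter shares kept their direction and side of the threshold, 14 lost a call, 3 gained one and 1 reversed. Of the 32 lists, 24 kept theirs under every alternative run. Lists above other genes numbered 7 to 10 against 8, and lists below 10 to 12 against 12. The squamous forestomach list lost its call by Fisher's exact test with a promoter of 500 bp (adjusted p = 0.185), with peaks in the upper part of the fold range (1), with peaks that both replicates overlapped (0.515), and without replicate 1 (0.376) or replicate 2 (0.102). By the same exact test, enteric neurons and glia lost theirs in the pooled list (adjusted p = 0.148, elsewhere 0.000741 to 0.00704), where endothelium gained one (0.00266, elsewhere 0.0828 to 0.497). The erythroid call was lost without replicate 1 (exact test, adjusted p = 0.0790), in the pooled list (0.0757), with folds in the upper part (0.128) and with peaks that both replicates overlapped (0.0768). Mesothelium lost its call without replicate 2 (exact test, adjusted p = 0.102) and in the last 2 of these settings (0.107 and 0.0511). Without replicate 2, germ cells lost theirs (exact test, adjusted p = 0.0564, elsewhere 0.00226 to 0.0145) and Hox 6 to 8 gained one (0.0435), as in the pooled list (0.0393). With folds in the upper part, immune cells reversed to 14.3%, below other genes (Fisher's exact test, adjusted p = 0.0230, elsewhere 0.0508 to 1). Of the 85 named genes with a promoter peak, 84 kept it with a promoter of 500 bp, all but Spi1. In the upper part of the fold range 79 kept it, and Cdh5, Fcer1g, Spi1, Vil1, Ager and Ckm lost it. Among peaks that both replicates overlapped 83 kept it, and Spi1 and Ager lost it. Of the 83 named genes without a promoter peak, 81 still had none at 2.5 kb.

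Of the acetylated lengths, 237 kept their call, 8 lost it, 10 gained one and 1 reversed, and smooth muscle, immediate early and Hox 1 to 5 genes kept theirs under every alternative run. Counting each peak for every start within 50 kb, which also counts peaks of neighbouring genes, left 19 lists as they were. Gastric epithelial transcription factors (adjusted p = 0.0549, not an exact test), mucous (0.0549), parietal (0.371), squamous (0.0832), fibroblast (0.262), Hedgehog (0.338) and Hox 9 to 13 genes (0.352) lost calls that they kept under the other alternatives (0.00107 to 0.0307), and chief cell genes reversed from a median of 0 to 6994 bp, above random lists (0.0462, elsewhere 0.456 to 1). Housekeeping and Hox 6 to 8 genes gained calls there and with matching on span. With every start counted, lists below random lists numbered 4 against 2. Their number was 1 with folds in the upper part and 2 to 4 without either replicate, where leaving out replicate 2 put enteroendocrine genes (adjusted p = 0.0463, range 0.0232 to 0.912, not an exact test) and Wnt antagonists (0.0122, range to 0.271) below. Of the 25 genes with the most acetylated length, 12 remained with every start within 50 kb, 16 with the nearest within 50 kb, 18 with folds in the upper part, and 20 and 22 without replicates 1 and 2.

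The share of peaks at promoters moved to 22.3% in the pooled list and 43.8% with folds in the upper part, and ranged from 21.6 to 30.5% without either replicate. The share of genes moved to 58.7 and 49.8% in the first 2 of these. Of the 25 leading domains, 13 remained when joined within 5 kb, 13 without promoter peaks, and 15 to 22 without either replicate.

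Overlap between replicates depended on its definition. The shares for replicates 1 and 2 were 31.6 and 51.2% with 50% reciprocal overlap, 60.7 and 91.6% with a −log10 q of at least 5, 66.2 and 74.4% with equal numbers of peaks, and 51.9 and 87.7% by summits within 250 bp. With 50% reciprocal overlap, unshared shares were 90.8% in the lowest and 21.9% in the highest quintile of replicate 1, and 70.8 and 17.5% in replicate 2. Spearman's rho was 0.589 in distal peaks, 0.806 with a −log10 q of at least 5 and 0.778 for −log10 p. Overlap, correlation and unshared peaks need both replicates, so none has a value without one of them.

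E-box, FOX and TEAD ratios stayed above 1 with intervals above 1 under every alternative run. At the summit the ratio was 0.970 for AP-1, 0.981 for SRF and 0.869 for KLF/SP. Against shuffled sequence it was 0.891 for SRF, 1.37 for CDX, 2.86 for KLF/SP, 1.56 for ETS and 1.44 for HOX/PBX, and AP-1 and SOX, at 1.04 and 1.02, were no longer called. KLF/SP ranged from 0.941 to 0.953 without either replicate and was above flanks with 400 bp (1.12) and folds in the upper part (1.14). CTCF was below flanks under 5 of 6 alternatives (0.333 to 0.514), not against shuffled sequence (1.11), and GATA above under 4 (1.13 to 1.22). MEF2 was not called in replicate 1 alone, nor SRF in replicate 2 alone. Families above flanks numbered 12 with windows of 400 bp against 7. Families below flanks, 0 in the report, numbered 2 with 400 bp, 3 at the summit, 1 with folds in the upper part and 1 to 3 without either replicate. HNF1, NFI, NR2F, RFX and p63 had too few flanking windows for a call. The unknown depth limits every statement about genes without a peak.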

Other observations

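Tests of the p-value limit and of the background level were chosen only after the result was seen, and long non-coding RNAs and transcription factor families were looked at without a plan, with the genes named from them chosen after their values were seen.

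Sequence near smooth muscle genes was compared with that in other distal peaks. A CArG box, bound by SRF, was present in 7 of 160 distal windows assigned to visceral smooth muscle genes (4.375%) and in 384 of the 36232 other windows (Fisher's exact test, two-sided, adjusted p = 0.00897 over 5 tests). This is consistent with SRF sites in enhancers of these genes, although windows of 1 gene are not independent and SRF binding was not measured. FOX sites near gastric epithelial transcription factors were present in 8.97% of 145 windows against 7.504% (Fisher's exact test, adjusted p = 0.876), and short GATA sites in 27.6% against 24.01% (adjusted p = 0.825), which left both open with so few windows. HOX/PBX sites near Hox genes of paralogs 1 to 5 were present in 0 of 20 windows, where fewer than 1 was expected. The p63 consensus was present in 0 windows, near squamous genes or elsewhere, so neither of the last 2 could be tested.

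Long intergenic non-coding RNA genes also carried promoter peaks. Of 5363 such genes more than 2.5 kb from a protein-coding start, 625 (11.7%) had one in the replicated list, 14.7% in replicate 1 and 10.4% in replicate 2. For a ranking by fold, genes with symbols beginning in Gm and digits, ending in Rik or naming a clone were left out. So were genes without a promoter peak in both replicates. Among the rest, the strongest were Malat1 with a fold of 39.9 (32.3 and 40.9 in the replicates) and Neat1 with 34.4 (28.1 and 32.2). They encode abundant nuclear RNAs. Both lie in 1 extended domain on chromosome 19 (5786611 to 5852442) with 37082 bp covered and no protein-coding start. They were followed by Lockd (24.6), Carmn, a smooth muscle RNA gene (22.97), and Mir17hg (18.04). Of the 2 leading extended domains on chromosome 12 without a protein-coding start, the one at 79879181 to 80018220 held the start of the non-coding gene 9430078K24Rik, and the one at 79429664 to 79560235 held none.

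Promoter peaks were counted in transcription factor families, without a test of a difference between them, where 55.4% of all protein-coding genes had one. The families were not matched on promoter CpG. Random lists matched on CpG had 67.5% for the gastric epithelial and 83.0% for the mesenchymal transcription factors, so 55.4% may be too low a reference. All 8 Smad, 4 Nfi and 4 Tead genes had one, as had 15 of 17 Klf genes, 5 of 6 retinoid receptor genes and 6 of 7 Meis and Pbx genes. The Nfi genes had a median acetylated length of 16229 bp and the Klf genes of 5978 bp. Of 6 Gata genes, Gata3, Gata4, Gata5 and Gata6 had a promoter peak and Gata1 and Gata2 did not. Of 44 Fox genes 24 had one, of 19 Sox genes 13, of 14 Nkx genes 4 (5 in replicate 1 and 2 in replicate 2) and of 16 genes with symbols beginning in Pou, the coactivator gene Pou2af1 included, 3 (5 and 3 in the replicates). Of 9 Pax genes the only one was Pax9, a gene of the foregut and squamous epithelium, and it had none in replicate 2.

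Fewer genes on the X chromosome than on autosomes had a promoter peak, 311 of 948 (32.8%) against 56.9%. Random autosomal genes with equally CpG-rich promoters had 45.8% (central 95% range 43.2 to 48.3%), and the difference of -13.0 percentage points argues against CpG content as the whole source. It was found in replicate 1 (36.4 against 49.5%) and in replicate 2 (31.9 against 44.2%). Where an X-linked gene had a promoter peak, its fold was lower, with a median of 7.23 against 9.002, a ratio of 0.803, and 0.757 and 0.812 in the replicates. Over the central 95% range of the random autosomal lists the ratio ran from 0.740 to 0.883. That range covers neither the sampling of X-linked genes nor the variation between animals. A candidate explanation is the smaller number of X copies with the mark in pooled males and females, since males carry 1 and females silence 1, but fewer copies of X DNA in the pool could also lower a fold taken over a genome-wide level. Gene content of the X other than promoter CpG was not matched, so it could also lie behind the lower share of genes with a peak. The design has no group by sex, so no biological explanation was tested.

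Replicate 1 held 1.62 times as many peaks as replicate 2, and they were weaker. Calls on noise as the whole source of replicate 1's unshared peaks were tested with AP-1 sites, as fixed beforehand. In unshared distal peaks of replicate 1 their ratio over flanks was 1.16 (1.09 to 1.248). This met the bound set against noise, an interval above 1. In the replicated list, however, the AP-1 ratio was 0.970 at the summit and 1.04 against shuffled sequence, where those of E-boxes and FOX sites stayed above 1. Both of these families, outside the fixed test, were also above flanks in unshared peaks. Their ratios were 1.22 (1.18 to 1.26) and 1.13 (1.08 to 1.19), and 1.21 and 1.18 in shared peaks. Flanks were matched on GC content only, and unshared peaks were not checked at the summit or against shuffled sequence. A difference from flanks therefore cannot decide whether noise was the whole source. A looser p-value limit is argued against by the lowest −log10 p of both lists, which differed by -0.0161. A background level recovered from the deposited p-values, tested on 3 simulated lists, was 1.68 times higher in replicate 1 (2.55 against 1.52 tags) and gave back the p-value of 99.8 and 99.9% of the peaks that it could be applied to, 66.5% of replicate 1 and 57.9% of replicate 2. A higher level lets smaller folds pass the same limit and may come from deeper sequencing, but the depth is unknown here, replicate 2's level before scaling was closer to replicate 1's (ratio 1.17), and no biological explanation was tested.

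The replicated list held 13740 peaks that the lists of the replicates did not both overlap, 10747 of them overlapped by replicate 1 alone, 2214 by replicate 2 alone and 779 by neither. Among pooled peaks not overlapped by both, those in the replicated list had the higher −log10 p, with a median of 5.31 against 3.84 for the 34767 others. The area under the curve was 0.804, just above the bound of 0.8 set for admission through strength in the pooled reads. All 42397 pooled peaks with at least 50% overlap of either peak in both replicates were in the list. Lists from random splits of the pooled reads, which might also admit such peaks, were not used here, and no biological explanation was tested.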
